A study of Mus musculus with 4 samples.

How the data were processed

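RNA from 4 heart samples of male mice, 2 WT and 2 endothelial S1pr1 knock-out, was measured 5 days after coronary ligation on 1-colour Agilent mouse arrays. Each sample's genotype and number were taken from its label (WT1, WT3, KO3 and KO4). That number is called the replicate here, although every label also ends in rep1. Per the labels' protocols, total RNA was extracted with Trizol, and labelled with Cy3 in an amplification for low RNA input. Per the file headers, spots were read with Feature Extraction 11.0.1.1, while the submitters' processing notes name Agilent Feature Extraction 9.1; which of these made each step was not settled. The scanner intensity used is the processed signal, which per the file headers was background-subtracted and spatially detrended within each array. Spot flags (well above background, saturated, outlier) are other values used as given per the file headers. The deposited value table holds log2 values; against log2 scanner signals its columns had slopes of 0.997 to 1.01. The lower quartile (2.87), median (6.106), upper quartile (9.746) and 99th percentile (15.69) were alike in all 4 columns, so between-array normalization had been applied, by a step not given in the sources used here.

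Control spots and outlier spots were left out, and spots of 1 probe were averaged on the log2 scale. Log2 processed signals were scaled by subtracting the 75th percentile of each array. No spot was saturated. Probes well above background on at least 2 of the 4 arrays were kept, whatever their genotype, and a gene with several probes was represented by the probe of highest mean. Of 39429 probes, 27234 were named through their RefSeq accession with 1 symbol of the GRCm38.p6 table (20659 genes), 0 had several symbols and 12195 had none and were tested under the identifier the array gives. The arrays' grid names the mm9 build, so no coordinates are printed, and the table served only for names, chromosomes and gene order.

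WT replicate 1 differed from the other arrays in its background. Its lowest processed signal was 10.2 (1.84, 1.45 and 1.34 on WT replicate 3, KO replicate 3 and KO replicate 4), and its negative controls had an SD of 6.79 (1.68, 1.46 and 1.17). Signal over background limits what can be said of dim genes, most of all there.

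KO was compared with WT by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Gene lists and cell type markers, fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, adjusted over 49 lists; 1 list (thymus, 4 members) was too small. Camera with an estimated correlation and fry are alternatives. The sign of the list mean differed from the direction of the test for 4 lists (endocardial, smooth muscle, B cell and hypoxia), and that of the median for 4 (endocardial, smooth muscle, B cell and cardiac stress). None of these was called. The named genes were also fixed by rule. They were S1pr1, up to 4 members of smallest p of each list described, and 22 genes chosen for the study's question. To these came the 12 genes in each direction with the largest change among those past the threshold. Places left were filled by smallest unadjusted p among genes at least 2-fold different. All of these 12 had a symbol, did not overlap between genotypes and were well above background on both arrays of the higher genotype. Gm, LOC, RIKEN clone and accession names were left out under this rule.

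The fit was tested on simulated data for KO minus WT with 22924 genes, 200 of them changed. At the spread fitted here it recovered 0 of 200 at each log2 change of 1, 2 and 4, with median estimates of 1.03, 2.01 and 3.94. At a spread 10 times smaller it recovered 95% at 1 and 99.5% at 2 and at 4. Camera called a median of 0 of 49 lists in 50 runs with independent genes and no change. In 50 runs without an added genotype effect, over the same 22924 genes, the arrays were placed at random along the main axis that separates them. Camera then called a median of 18.5 lists, and 0 at the lowest. The axis was taken from these data, so it may hold part of a genotype effect.

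Alternatives tried were quantile and median scaling, no filter and a stricter filter on dim probes, the deposited values, the mean of a gene's probes, eBayes with trend and robust options, an adjusted p under 0.10, each array left out, and, chosen after seeing the data, normexp on median signals with an offset of 50, a common floor under dim signals, the cardiomyocyte marker mean as a covariate, and the arrays numbered 3 alone.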

Results

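The series profiled hearts of male mice 5 days after ligation of the left anterior descending coronary artery, an operation that causes a myocardial infarction. Hearts of wild-type mice (WT) were set against hearts of knock-out mice (KO). In these, a Cre recombinase driven by the VE-cadherin promoter is meant to remove the floxed S1pr1 gene from endothelial cells. Which cells lost the gene was not measured here. S1pr1 encodes a receptor for the blood lipid sphingosine 1-phosphate. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, with 2 arrays per genotype: WT replicates 1 and 3, and KO replicates 3 and 4. The labels do not say whether each array is a separate heart, so p-values measure only the spread between these samples, which may be technical. All 4 arrays lay on 1 slide and were read in 1 scan. WT replicate 1, WT replicate 3, KO replicate 3 and KO replicate 4 lay at positions 4, 3, 2 and 1. An effect of position on the slide therefore cannot be told apart from genotype. The share of probes well above background was 54.3% in WT replicate 1, 69.4% in WT replicate 3, 73.4% in KO replicate 3 and 71.5% in KO replicate 4. The number of arrays limits the precision of every value below. Levels are log2 signals relative to the 75th percentile of their own array, and differences are KO minus WT on the log2 scale. The male label was checked first: Ddx3y, Uty and Eif2s3y, which lie on the Y chromosome, were well above background on 4 arrays, while the Y-linked Kdm5d and the 2 probes for Xist were above it on 0.

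The comparison asked how loss of endothelial S1pr1 changes gene expression in the infarcted heart. S1pr1 itself was lower on both KO arrays. Its level was 0.69 ± 0.37 in WT and -2.49 ± 0.28 in KO (SD, n = 2 each), a difference of -3.19 (SE 0.38, 95% interval -4.20 to -2.18). This is 9.098-fold, with an interval of 4.52-fold to 18.3-fold. The array values were 0.43 and 0.95 in WT against -2.69 and -2.30 in KO, and the S1pr1 probe was well above background on all 4 arrays, so signal remained in KO hearts. S1pr1 ranked 6 among 22924 tested features by unadjusted p, which was 0.000714 in limma, and its adjusted p was 0.740. An exact two-sided permutation test of 2 against 2 arrays gave p = 0.333, the smallest value that design allows. The position of the single S1pr1 probe relative to the deleted part of the gene was not determined here.

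**Figure D1:**
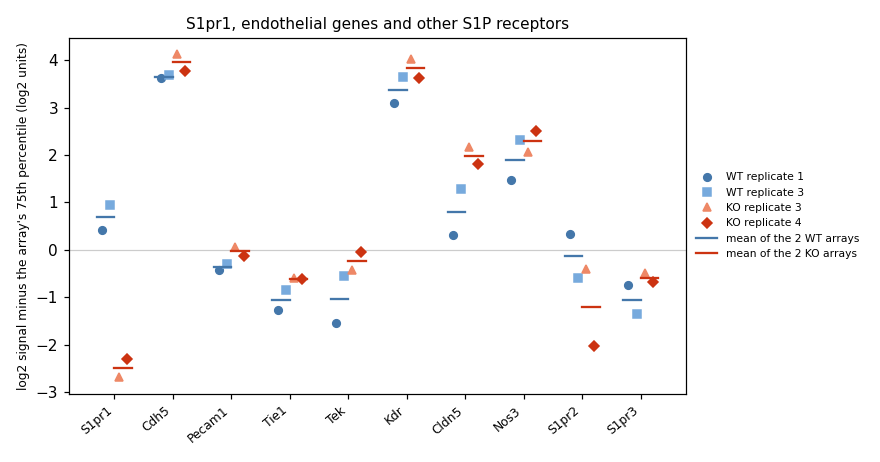
Level of S1pr1, of 7 endothelial genes and of the S1P receptors S1pr2 and S1pr3 on each array, as log2 signal minus the 75th percentile of the array. Points are single arrays and lines are the means of 2 arrays; the S1pr1 values of the KO arrays, -2.69 and -2.30, lie below those of the WT arrays, 0.43 and 0.95.

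The other S1P genes named in advance did not pass the test. The S1P receptor S1pr2 differed by -1.09 (SE 0.70), S1pr3 by 0.47 (SE 0.37) and Sphk1, a kinase that makes sphingosine 1-phosphate, by -0.87 (SE 0.50). Of the 13 tested genes for S1P receptors and metabolism, 9 were lower and 4 higher in KO. S1pr1 was the only member to pass when adjusted over the list alone (adjusted p = 0.00928 in limma), and none passed over all features. The list was not called (mean difference -0.36, median -0.28, camera adjusted p = 0.0698). Its mean and test include S1pr1 itself, at -3.19. Endothelial markers were not reduced with S1pr1: Cdh5, the adhesion protein whose promoter drives the Cre, differed by 0.30 (SE 0.33) and Pecam1 by 0.33 (SE 0.31).

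No gene passed the test between genotypes. At an adjusted p under 0.05 limma called 0 features higher and 0 lower in KO among 22924 tested, 15952 of them with a gene symbol, and the smallest adjusted p was 0.642. Without correction, 632 features (2.76%) had a p under 0.05, of which 292 were at least 2-fold higher and 298 at least 2-fold lower. These counts were 177 and 648 without the filter on dim probes, 52 and 68 with a common floor under dim signals, 2853 and 1397 without WT replicate 3, 336 and 977 without KO replicate 3, and 68 and 98 without KO replicate 4. The genotypes did not overlap for 34.4% of features, where chance gives 33.3%. On data simulated with the spread fitted here, 0 of 200 genes changed by 4 on the log2 scale were recovered, so the count of 0 does not show that expression was alike.

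The arrays did not group by genotype. WT replicate 3 and KO replicate 3 were the closest pair (Pearson r across genes 0.986, where genes are not independent replicates), the WT arrays correlated at 0.941 and the KO arrays at 0.965, and WT replicate 1 and KO replicate 4 were the least alike at 0.882. Component 1 of a principal component analysis held 79.6% of the variance and placed WT replicate 1 at -140, KO replicate 3 at 5.79, WT replicate 3 at 22.2 and KO replicate 4 at 112.

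The genes with the smallest unadjusted p under the naming rule are given as values, since none passed the correction. Their adjusted p was 0.740 each in limma. The rule leaves out clone names such as 2310065F04Rik, which differed by 5.58 and had a smaller unadjusted p in limma (2.8e-05) than any of them. Among the rule's genes lower in KO, Rpgrip1, a protein of the photoreceptor cilium, had the smallest p, 8.12e-05. It was 2.97 ± 0.63 in WT and -3.10 ± 0.06 in KO. Samd4, an RNA-binding translational repressor, was 1.95 ± 0.18 in WT and -2.34 ± 0.16 in KO. The amino acid transporter Slc7a8 differed by -4.18 (SE 0.66), and the high-affinity Fc receptor Fcgr1 by -2.82 (SE 0.52). The Schlafen genes Slfn3 and Slfn4, which are close in sequence and may share signal, differed by -3.39 and -4.34, and Clca3a1 by -2.04. The epithelial barrier genes Crct1 and Scel differed by -6.07 and -2.30, with Crct1 well above background on only 1 of the KO arrays. Sprr2g and the phosphatase Ptpn5 were not well above background on either KO array, so only bounds can be given: at least 20.5-fold lower for Sprr2g and at least 4.72-fold lower for Ptpn5. These bounds set the mean of the brighter genotype against the lowest signal well above background on each dim array.

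Among the genes higher in KO, Ren1, which encodes renin, differed by 3.06 (SE 0.46), from -4.94 ± 0.68 in WT to -1.88 ± 0.26 in KO. It was well above background on 1 of the WT arrays, as were Adcy1 (difference 3.13), Scgb1b29 (2.82), Tmc5 (2.06) and Pcdh20 (1.55, in log2 units as the others). On WT replicate 1 their levels were -5.43, -6.66, -4.79, -6.65 and -6.74, with Ren1 first. All lay below the lowest signal well above background on that array (-4.389). The sizes of these differences rest in part on such dim values and are uncertain. The kinase Pi4kb and the endosomal GTPase Rab4a, well above background on all 4 arrays, differed by 1.52 and 1.73. The glycine receptor subunit Glrb was at least 4.19-fold higher and was not well above background on either WT array. Nor were Bcl11b, Cadm2, Olfr1136 and Kcnc1, for which the same bound on group means gave 1.61-fold, 1.55-fold, 1.504-fold and 1.19-fold. Both KO values of these genes, and of Pcdh20, lay below the lowest signal well above background on WT replicate 1 (-4.389). That array therefore cannot show a rise for them, and the bounds rest on WT replicate 3. In a setting chosen after seeing the data, all signals were raised to the floor of the least sensitive array. There, 5 of the 23 genes named by rule in these paragraphs had no difference of the same sign left. These were Bcl11b, Cadm2, Olfr1136, Kcnc1 and Pcdh20.

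Gene lists fixed before the data were examined were compared as groups. Of 49 tested lists, limma's camera with a preset correlation called 8 higher and 15 lower in KO. With a correlation estimated from the residuals it called 0, and each of the 23 called lists then had an adjusted p = 0.677 with an estimated correlation. The rotation test fry, which asks whether a list moves one way without comparing it with other genes, also called 0 (smallest adjusted p = 0.732). Apart from S1pr1 in its own list, no member of any list passed the gene test over all features or adjusted over the list alone. In 50 simulated runs over 22924 genes without an added genotype effect, the arrays were placed at random along the axis that separates them. Camera with the preset correlation then called a median of 18.5 of 49 lists (lowest 0). That axis was taken from these data and may hold part of a genotype effect. The calls in the real data thus describe the arrays and do not by themselves tie a list to genotype. The genotypes' arrays were separate in the list mean for 8 of the 23 called lists. With 2 against 2 arrays chance separates a value in 33.3% of cases, so this count does not tie these lists to genotype.

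Genes induced by interferon were lower in KO as a group. All 25 measured members had a lower mean in KO, by 1.15 on average (SD over genes 0.49), and the list mean was 1.27 and 2.28 on the WT arrays against 1.12 and 0.13 on the KO arrays. The antiviral enzymes Oas2 (-1.20, SE 0.36), Oasl2 (-1.62, SE 0.54) and Oasl1 (-1.75, SE 0.59) and the nucleic acid sensor Zbp1 (-2.01, SE 0.64) had the smallest p. For 13 of the 25 genes the arrays of the genotypes did not overlap, as for 34.4% of all features. The list's genes vary together (estimated correlation 0.91), so these are not 13 separate results. The list had the smallest adjusted p of all with camera, 5.03e-11, and adjusted p = 0.677 with an estimated correlation. Leaving out WT replicate 3 or KO replicate 4 reduced the mean difference to -0.64 and -0.65, with camera adjusted p = 0.00494 and 1.06e-07. The pan-macrophage list mean was also lower on the KO arrays, at 2.03 and 0.26 against 3.23 and 2.24.

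**Figure D2:**
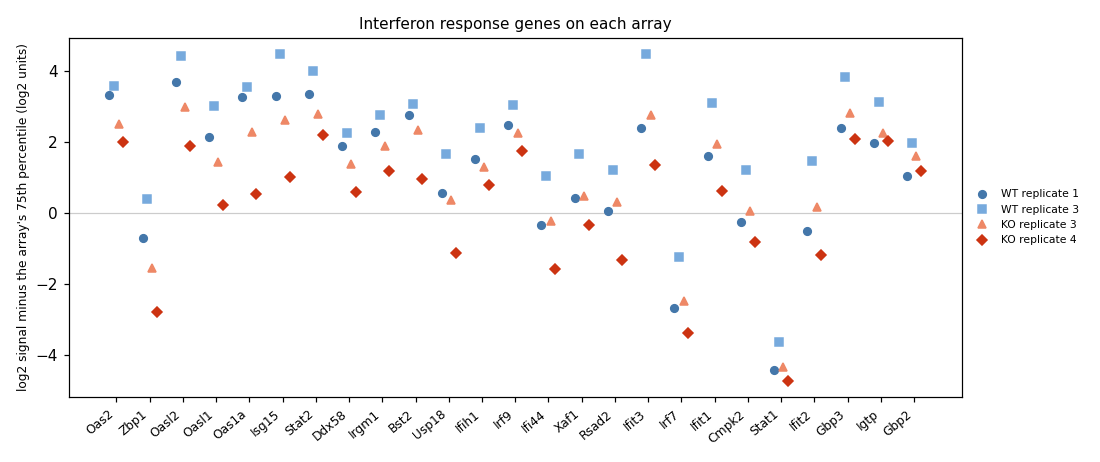
Level of each of the 25 interferon response genes on each array, as log2 signal minus the 75th percentile of the array. Each point is 1 array; the list mean is 1.27 and 2.28 on the WT arrays and 1.12 and 0.13 on the KO arrays.

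Macrophage and monocyte genes were also lower in KO. The 17 pan-macrophage genes were all lower, by 1.60 on average, with list means of 3.23 and 2.24 in WT against 2.03 and 0.26 in KO. Fcgr1, Aif1 (-1.70), the galectin Lgals3 (-3.55) and the pore-forming protein Mpeg1 (-2.44) had the smallest p (camera adjusted p = 7.17e-07, and adjusted p = 0.677 with an estimated correlation). Of 18 inflammatory monocyte and macrophage genes, 16 were lower, by 1.56 on average over the list, among them Chil3 (-3.52), Plac8 (-3.02), the chemokine receptor Ccr2 (-2.52) and the chemokine Ccl3 (-1.92). Their camera adjusted p was 3.85e-06, and adjusted p = 0.677 with an estimated correlation. WT replicate 3 and KO replicate 3 differed little in these lists: KO minus WT within that pair was -0.22 for the pan-macrophage genes and 0.18 for the inflammatory genes. Without KO replicate 4 the list differences were -0.71 and -0.46, without KO replicate 3 they were -2.48 and -2.67, and without WT replicate 1 the inflammatory genes differed by -0.92. The ventricular cardiomyocyte mean moved the other way, at 1.45 and 5.71 in WT against 5.34 and 6.20 in KO. Ccl2, which attracts monocytes, differed by -1.27 (SE 0.65). Ly6c2 had no probe named here.

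The CSF1 list, genes through which macrophages receive growth signals, was called lower (10 of 12 members, mean -0.80, camera adjusted p = 0.00258, and adjusted p = 0.677 with an estimated correlation). The members of smallest p were Trem2 (-2.55), Csf2ra (-1.29), Inpp5d (-1.18) and Spi1 (-1.37). Csf1 itself differed by -0.04 (SE 0.38) and its receptor Csf1r by -0.25 (SE 0.47). The list was not called without WT replicate 1 (mean -0.33, adjusted p = 0.133), and its mean was -0.45 without KO replicate 4 and -1.27 without WT replicate 3. The 20 reparative and resident macrophage genes were not called: 11 were lower and 9 higher, with a mean of -0.19 (camera adjusted p = 0.518), which was 0.14 without WT replicate 1 and -0.52 without WT replicate 3. Chil3, also in the inflammatory list, had the smallest p of the reparative genes and differed by -3.52. Mrc1, a receptor of reparative macrophages, differed by -0.30 (SE 0.40), and Cd163 by 1.51 (SE 0.70). Il10 differed by -1.07 and Pf4, also a platelet marker, by -1.49. Cd163 and Il10 were well above background on only 1 of the WT arrays. Arg1 spanned a wide range within each genotype, 2.89 and -0.91 in WT and 1.92 and -5.38 in KO.

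All 30 proliferation genes were lower in KO, by 2.04 on average (camera adjusted p = 6.24e-11, and adjusted p = 0.677 with an estimated correlation). Their mean was 1.59 and 0.36 on the WT arrays and 0.44 and -2.57 on the KO arrays, so WT replicate 3 and KO replicate 3 lay within 0.08 of each other. The mitotic kinase Plk1 differed by -3.02 (SE 1.48), Kif20a by -2.73, the replication helicase subunits Mcm6 by -1.52 and Mcm4 by -1.44, and Mki67 by -2.07 (SE 1.35). Without KO replicate 4 the mean difference of the list was -0.53 (camera adjusted p = 1.22e-05), and without KO replicate 3 it was -3.55. Pan-macrophage markers had the same lowest array, KO replicate 4, at 0.26.

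Extracellular matrix genes were lower in KO for 23 of 28 members, by 1.31 on average over the list. The list means were 3.79 and 3.25 in WT and 3.36 and 1.06 in KO. Ccn2 (-1.31), the crosslinking enzyme Lox (-3.24), Thbs2 (-1.78) and Col5a1 (-2.10) had the smallest p, and Col1a1, Col3a1 and Postn differed by -0.66 (SE 0.62), -0.67 (SE 0.56) and -1.69 (SE 1.27). The camera adjusted p was 6.32e-06, and adjusted p = 0.677 with an estimated correlation; without KO replicate 4 the list was not called (mean -0.16, adjusted p = 0.379), and without KO replicate 3 its mean was -2.46. Myofibroblast genes followed the same arrays (9 of 11 lower, mean -1.57, camera adjusted p = 0.00855, and adjusted p = 0.677 with an estimated correlation), with Tnc at -3.94 (not well above background on KO replicate 4) and Cthrc1 at -3.84, and were not called without KO replicate 4 (mean -0.13, adjusted p = 0.783), while without KO replicate 3 the mean was -3.00. Pan-macrophage markers were likewise lowest on KO replicate 4, at 0.26. Fibroblast markers were not called (mean 0.13, camera adjusted p = 0.919); without KO replicate 4 they were called higher (0.37, adjusted p = 0.0349), and without KO replicate 3 the mean was -0.11.

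Matrix-degrading proteases and their inhibitors were lower for 17 of 20 members (mean -1.17), including Mmp8 (-2.21), Plau (-1.60) and Mmp13 (-0.84). TGF-beta signalling genes were lower for 15 of 18 (mean -0.80), with Tgfbi at -2.04 and Pmepa1 at -1.09, and genes of the unfolded protein response for 14 of 18 (mean -0.64), with Atf3 at -1.39 and Calr at -0.93. Their camera adjusted p-values were 5.10e-05, 0.00258 and 0.00258, each with adjusted p = 0.677 with an estimated correlation. The unfolded protein response was not called without WT replicate 1 (mean -0.15, adjusted p = 0.252), and its mean was -0.41 without KO replicate 4 and -1.13 without WT replicate 3. The protease and TGF-beta lists differed by -0.56 and -0.36 without KO replicate 4, by -0.70 and -0.45 without WT replicate 1, and by -1.79 and -1.24 without KO replicate 3. Pan-macrophage markers were lower on the KO arrays too, at 2.03 and 0.26 against 3.23 and 2.24.

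Lists of ventricular cardiomyocyte, contraction, ion channel and mitochondrial metabolism genes were called higher in KO, and WT replicate 1 stood apart in all of them. All 16 ventricular cardiomyocyte markers had a higher mean in KO, by 2.19 on average, with list means of 1.45 and 5.71 in WT against 5.34 and 6.20 in KO. The creatine kinases Ckm and Ckmt2 differed by 3.88 (SE 2.31) and 2.91 (SE 1.82), and Myh6, the main adult myosin heavy chain of the mouse ventricle, by 1.89 (SE 1.24). All 22 sarcomere genes (mean 2.03), all 33 genes of oxidative phosphorylation (1.37), all 18 of the TCA cycle (1.39), 27 of 28 of fatty acid oxidation (1.63) and 19 of 20 cardiac ion channel genes (1.65) were higher, with examples Ttn (2.003), Ogdh (1.56), Ppargc1a (3.36) and Kcnd2 (3.10, not well above background on WT replicate 1). Camera adjusted p-values were 0.000196 for the markers and 9.09e-06, 7.17e-07, 4.99e-05, 1.11e-05 and 0.000193 for the other lists in that order, all with adjusted p = 0.677 with an estimated correlation. Without WT replicate 1 none of these 6 lists was called: the cardiomyocyte markers then differed by 0.06 (adjusted p = 0.720), the sarcomere genes by 0.16 (0.360), oxidative phosphorylation by 0.16 (0.317), the TCA cycle by 0.20 (0.317), fatty acid oxidation by 0.14 (0.538) and ion channels by 0.22 (0.420). Without WT replicate 3 the differences were 4.32, 3.90, 2.58, 2.59, 3.11 and 3.07 in that order, and without KO replicate 4 oxidative phosphorylation, the TCA cycle, fatty acid oxidation and ion channels differed by 0.88, 0.89, 1.07 and 1.09.

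Glycolysis genes were not called (15 of 20 higher, mean 0.78, camera adjusted p = 0.121), and their members of smallest p, Pgam1 and Slc2a1, were lower (-0.86 and -0.68). Atrial cardiomyocyte markers were not called (7 of 10 higher, mean 0.59, camera adjusted p = 0.203). Glycolysis was called higher without WT replicate 3 (1.48, adjusted p = 0.00494), and the atrial markers without KO replicate 4 (0.56, 0.0376). Without WT replicate 1 their means were 0.0863 and 0.085, and the atrial mean was 1.09 without WT replicate 3.

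The cardiac stress and fetal programme was not called (mean -0.01, camera adjusted p = 0.752). The natriuretic peptides Nppa and Nppb differed by -0.43 (SE 1.18) and 0.27 (SE 1.16), and Myh7 by 1.12 (SE 1.96). Without KO replicate 4 this list was called higher (mean 0.53, adjusted p = 0.0376), and lower without KO replicate 3 (mean -0.54, adjusted p = 0.0481) and without WT replicate 1 (mean -0.65, adjusted p = 0.00187).

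**Figure D3:**
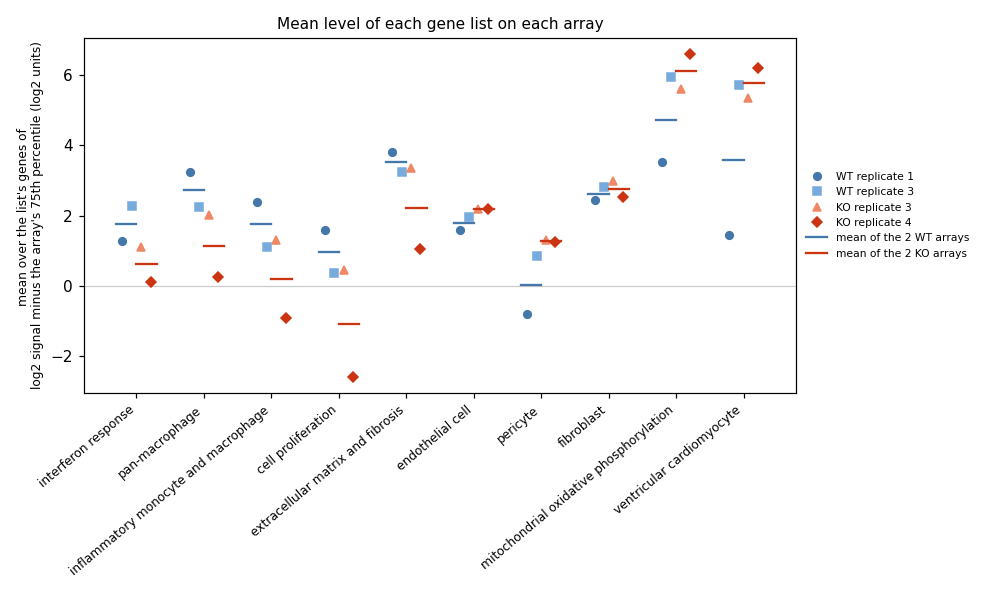
Mean level of 10 gene lists on each array, as the mean over genes of log2 signal minus the 75th percentile of the array. Points are arrays and lines are means of 2 arrays; in the ventricular cardiomyocyte list WT replicate 1 lies at 1.45 and the other arrays between 5.34 and 6.20, and in the proliferation list KO replicate 4 lies at -2.57 and the others between 0.36 and 1.59.

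Of the vessel lists, those of endothelial and pericyte markers were called higher in KO. Endothelial markers were higher for 19 of 20 members, by 0.40 on average, with list means of 1.60 and 1.97 in WT and 2.18 and 2.20 in KO. The junction protein Cldn5 differed by 1.19 (SE 0.47), the water channel Aqp1 by 1.24 (SE 0.65) and the receptor Tek by 0.81 (SE 0.47). Pericyte markers were higher for 9 of 10 members, by 1.26 on average (-0.79 and 0.84 in WT, 1.32 and 1.24 in KO), including Steap4 (1.15), the channel subunit Kcnj8 (2.07) and Vtn (1.94). Camera adjusted p-values were 0.00935 and 0.00258, each with adjusted p = 0.677 with an estimated correlation. The endothelial list was not called without WT replicate 1 (mean 0.22, adjusted p = 0.104) or KO replicate 3 (0.201), nor the pericyte list without KO replicate 3 (0.0640). The pericyte mean was 0.44 without WT replicate 1 and 2.07 without WT replicate 3. Ventricular cardiomyocyte markers were also lowest on WT replicate 1, at 1.45.

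Smooth muscle markers were not called (6 of 10 higher, mean 0.00399, camera adjusted p = 0.912), with Cnn1 at -2.41 and Tagln at -1.69. Their mean was -0.10 without WT replicate 1, 0.11 without WT replicate 3, -0.062 without KO replicate 3 and 0.070 without KO replicate 4. Angiogenesis genes were not called (16 of 27 higher, mean 0.20, camera adjusted p = 0.449), with Notch1 at 1.68 (SE 0.61), Pgf at -0.89 (SE 0.31) and Vegfa at 1.01 (SE 0.59). The list of AKT, nitric oxide synthase and shear-responsive genes was not called either (mean 0.17, adjusted p = 0.366): Nos3, the endothelial nitric oxide synthase, differed by 0.39 (SE 0.44), and the shear-responsive factors Klf2 and Klf4 by 0.83 (SE 0.46) and 1.29 (SE 0.40). Lists of endothelial junction (mean 0.26, adjusted p = 0.276) and endothelial activation genes (0.12, adjusted p = 0.752) were not called. Endothelial activation genes were called higher without WT replicate 1 (0.37, adjusted p = 0.0366) and averaged -0.13 without WT replicate 3 and -0.10 without KO replicate 4. The junction genes averaged 0.11 without WT replicate 1 and 0.41 without WT replicate 3.

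Several blood and surface cell types were called lower: platelet markers (7 of 8 lower, mean -1.31, camera adjusted p = 0.00181), erythroid markers (8 of 10, -0.65, 0.0135), epicardial and mesothelial markers (8 of 11, -0.51, 0.0140), NK cell markers (7 of 8, -0.91, 0.0310) and dendritic cell markers (10 of 13, -0.70, 0.0481). Each had adjusted p = 0.677 with an estimated correlation, and none of them but the platelet list was called without WT replicate 1, where the erythroid list had adjusted p = 0.0710, the NK cell list 0.241, and the epicardial and dendritic lists 0.981. The platelet list was not called without KO replicate 3 (adjusted p = 0.0652), nor the erythroid list (0.201), and the NK cell and dendritic lists were not called without KO replicate 4 (0.511 and 0.519). The platelet, erythroid, NK cell, epicardial and dendritic means were -0.43, -0.20, -0.34, 0.00691 and -0.0688 without WT replicate 1, and -2.19, -1.10, -1.49, -1.025 and -1.34 without WT replicate 3. Without KO replicate 3 the NK cell and dendritic means were -1.62 and -1.25, and without KO replicate 4 -0.21 and -0.16. Pan-macrophage markers were lower on the KO arrays too, at 2.03 and 0.26 against 3.23 and 2.24. Neutrophil (mean -0.32, adjusted p = 0.569), T cell (0.01, 0.848), hypoxia (-0.00431, 0.949) and ribosomal protein genes (-0.13, 0.0571) were not called. Nor were cytokines and chemokines (-0.37, 0.0698), skeletal muscle (0.98, 0.190), lymphatic endothelial (0.55, 0.261), lung epithelial (0.39, 0.265), immediate early (-0.24, 0.318), Schwann cell (0.30, 0.366), mast cell (0.29, 0.471), endocardial (0.20, 0.518), adipocyte (-0.41, 0.636), complement (-0.16, 0.752) and B cell genes (-0.17, 0.918).

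Leaving out an array called some of these lists: neutrophil genes higher without WT replicate 1 (0.59, adjusted p = 0.00638) and lower without WT replicate 3 (-1.22, 0.00594), T cell genes higher without KO replicate 4 (0.36, 0.0349) and ribosomal protein genes lower without KO replicate 4 (-0.20, 0.0289). Cytokines and chemokines were called lower without WT replicate 3 (-1.08, adjusted p = 0.00321) or KO replicate 3 (-1.06, 0.000499). B cell genes were called higher without WT replicate 1 (0.98, 0.0324) or KO replicate 4 (1.16, 0.00168), skeletal muscle genes without WT replicate 3 (1.82, 0.0262) or KO replicate 4 (1.11, 0.00164), and mast cell genes without WT replicate 1 (0.70, 0.00826). Endocardial genes were called lower without KO replicate 4 (-0.42, 0.0126). With WT replicate 1, WT replicate 3, KO replicate 3 and KO replicate 4 left out, in that order, the list means were 0.59, -1.22, -0.39 and -0.24 for neutrophil genes, 0.25, -0.24, -0.35 and 0.36 for T cell genes, 0.98, -1.31, -1.49 and 1.16 for B cell genes, and 0.70, -0.13, 0.44 and 0.13 for mast cell genes. In the same order they were 0.34, -1.08, -1.06 and 0.32 for cytokine and chemokine genes, 0.33, -0.65, -0.29 and -0.0249 for complement genes, 0.0156, -0.49, -0.45 and -0.0232 for immediate early genes, -0.19, 0.19, 0.0360 and -0.0447 for hypoxia genes, and -0.0429, -0.21, -0.0569 and -0.20 for ribosomal protein genes. For tissue markers they were -0.10, 0.51, 0.83 and -0.42 for endocardial genes, 0.26, 0.84, 0.81 and 0.30 for lymphatic endothelial genes, 0.14, 1.82, 0.85 and 1.11 for skeletal muscle genes, 0.53, -1.35, -0.87 and 0.0464 for adipocyte genes, -0.0146, 0.62, 0.51 and 0.0970 for Schwann cell genes, and 0.26, 0.52, 0.72 and 0.0586 for lung epithelial genes.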

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

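The normexp correction on median signals, the common floor, the cardiomyocyte covariate and the comparison of the arrays numbered 3 were chosen after seeing the data. No gene passed an adjusted p of 0.05 in any setting with a test; the smallest adjusted p ranged from 0.132 (without WT replicate 3) to 1. S1pr1 stayed lower in KO in every setting, at -2.69 to -3.65 with all arrays or the arrays numbered 3 (-3.65 for those alone) and at -3.45 to -2.92 with an array left out, and its adjusted p ranged from 0.135 to 1. Where an array was left out, the lone sample of its genotype was assumed to vary like the other genotype. Counts without correction depended on dim probes and on single arrays. Features at least 2-fold higher numbered 292, and 177 without a filter, 116 with the strict filter and 52 with the floor; those lower numbered 298, and 648 without a filter and 68 with the floor. Leaving out an array gave 68 to 2853 higher and 98 to 1397 lower. The higher share of these features was 49.5%, and 21.5% without a filter, 25.6% without KO replicate 3, 31.9% with the strict filter, 67.1% without WT replicate 3 and 38.0% with median scaling. Median scaling moved the median of all features from 0.07 to -0.04; normexp moved it to 0.14. The lists called higher numbered 8, and 5 to 14 with an array left out; those called lower numbered 15, and 10 to 17 with an array left out and 8 without a filter. Both counts were 0 with an estimated correlation and with fry. Of the 23 called lists, 22 were called the same way under quantile, median and deposited values, 18 with the floor, 16 without a filter, 11 with the cardiomyocyte covariate and 10 without WT replicate 1. Lists of pan-macrophage, inflammatory monocyte and macrophage, proliferation, protease and interferon genes were called lower in each of 14 settings with the preset correlation. Directions turned for 15 of the 23 called lists between the arrays numbered 3: CSF1 0.0200, inflammatory 0.18, proliferation 0.0831, matrix 0.11, sarcomere -0.20, oxidative phosphorylation -0.33, fatty acid oxidation -0.41, TCA cycle -0.30, unfolded protein response 0.0789, ion channels -0.33, ventricular cardiomyocyte -0.37, myofibroblast 0.14, epicardial 0.14, dendritic 0.47 and NK cell 0.36. Among lists called in at least 1 of the compared settings, directions also turned with the cardiomyocyte covariate for complement (0.35), epicardial (0.0272), neutrophil (0.60), dendritic (0.0310) and adipocyte genes (0.61). Without WT replicate 1 they turned among such lists for epicardial (0.00691), neutrophil (0.59) and dendritic genes (mean -0.0688, with a positive test direction), which without WT replicate 3 differed by -1.025, -1.223 and -1.337. Of such lists the cardiac stress programme turned without KO replicate 4 (0.53); it was -0.65 without WT replicate 1 and 0.63 without WT replicate 3. Of 225 named genes besides S1pr1, 66 changed or lost their direction between the arrays numbered 3. The number was 14 with the floor, 13 with the cardiomyocyte covariate and 12 without WT replicate 1. Beyond the fewer arrays or genes that a setting uses, the cause of these turns was not tested. The planned normexp on mean signals was not run, since the columns used here hold median signals, nor were a slide block, with 1 slide, and other S1pr1 probes, with 1 probe. No paired analysis was possible because the genotypes share only the number 3, and the labels do not say that it pairs samples. Signal over background, lowest on WT replicate 1, limits all statements on dim genes.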

Other observations

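The tests of cardiomyocyte share, injured tissue, macrophage content, chromosomes and neighbouring genes were chosen after the results were seen, as was the use of the strict filter as a test of background; that filter and the other groupings of the arrays were planned. Some marker genes varied between arrays without following genotype. B cell and plasma cell markers averaged -1.17 on WT replicate 1 and -1.15 on KO replicate 3, against -3.46 on WT replicate 3 and -3.81 on KO replicate 4. Adipocyte markers averaged 0.34 and -1.54 in WT and -0.55 and -1.47 in KO.

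Other groupings of the 4 arrays gave as many list calls. The real grouping had 632 features at an unadjusted p under 0.05 and 23 called lists. Setting WT replicate 1 with KO replicate 3 gave 1073 features and 27 lists, and setting WT replicate 1 with KO replicate 4 gave 140 features and 26 lists. The interferon list had a camera adjusted p of 5.03e-11 in the real grouping, 0.795 in the grouping of WT replicate 1 with KO replicate 3, and 4.76e-20 with KO replicate 4, a smaller value than for genotype. With 3 groupings no share under 0.05 can be had.

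Lower injury genes and higher cardiomyocyte genes in KO form the main pattern, with WT replicate 1 and KO replicate 4 at its ends. Its parts rest on different arrays. Ventricular cardiomyocyte markers set WT replicate 1 apart (1.45, against 5.71 on WT replicate 3 and 5.34 and 6.20 in KO). Matrix genes set KO replicate 4 apart (1.06, against 3.36 on KO replicate 3 and 3.79 and 3.25 in WT). A different share of cardiomyocytes alone would move all other cell types alike. The pan-macrophage genes moved by -2.85 relative to the pericyte genes (SE over genes 0.46). This pair of lists was picked after seeing the data, and fibroblast and smooth muscle means (0.13 and 0.00399) lay between them. Pericyte markers, like cardiomyocyte markers, were lowest on WT replicate 1 (-0.79). The SE also treats genes that vary together as independent, so the gap does not exclude cardiomyocyte share. With the cardiomyocyte mean as a covariate the pan-macrophage and pericyte lists stayed called at -0.93 and 0.46. Of the 23 called lists, 11 stayed called. That count decides nothing, since the covariate is built from the cardiomyocyte markers and removes them and lists that track them. Over genes well above background on all 4 arrays, 22 of 23 lists were called the same way, so the calls did not rest on dim genes. Camera with the preset correlation also called lists in simulations without an added genotype effect. These calls alone therefore do not exclude the higher background of WT replicate 1 as a cause. Unequal amounts of injured tissue between hearts or pieces, whatever the genotype, remain a candidate explanation: the median absolute difference of the called lists was 0.22 between the arrays numbered 3, 1.27 between arrays of 1 genotype and 1.31 between genotypes. With 2 arrays per genotype this cannot be told apart from an effect of S1pr1 on the size or stage of the injury, which stays open.

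Interferon genes broke from that pattern on WT replicate 3 and may be a candidate for a difference tied to genotype, although a grouping across genotypes gave it a smaller p. Macrophage content as the cause stays open: from WT replicate 1 to WT replicate 3 the interferon mean changed by 1.01 (SE over genes 0.10) while the pan-macrophage mean changed by -0.98 (SE 0.11), and between KO replicate 3 and WT replicate 3 the interferon difference exceeded the macrophage difference by -0.94 (SE 0.26). Each of these contrasts rests on WT replicate 3, and the other 3 arrays run in the same order in the interferon (1.27, 1.12 and 0.13) and pan-macrophage means (3.23, 2.03 and 0.26). A difference in interferon tone between individual hearts unrelated to S1pr1 was not tested and stays open beside genotype.

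Genes that separated the genotypes (unadjusted p under 0.05, at least 2-fold, not overlapping) were unevenly placed in the genome. They made up 5.49% of tested genes on chromosome 14 and 5.00% on chromosome 3, which carries S1pr1, against 2.58% of all genes. The adjusted p was 0.000706 for each (one-sided Fisher's exact test over 20 chromosomes, with neighbouring genes not independent). In the other groupings of the arrays the smallest unadjusted p of either chromosome in this test was 0.121. Both were picked for standing out in the real grouping, and no other chromosome was tested in those groupings. This comparison therefore cannot show whether the uneven placing is particular to genotype. Sequence of the donor strain carried along with the floxed allele could place such genes next to S1pr1, yet 23.6% of windows of 100 neighbouring genes held as many as the 4 around S1pr1, which decides neither way. The densest window, with 12, lay around Parp2 on chromosome 14, where Samd4 and Slc7a8 lie -46 and 24 tested genes from Rpgrip1. Some of the separating genes belong to macrophage lists called lower, such as Fcgr1 and Chil3 on chromosome 3 and Lgals3 on chromosome 14. Others are neighbours of similar name, such as Clca3a1 and Clca3a2. How far these account for the uneven placing was not tested. Strain differences elsewhere in the genome, including probes that bind one allele poorly, were not tested either.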
